A study of Mus musculus with 9 samples.

How the data were processed

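The series measured RNA by sequencing in primary mouse airway basal stem cells, the progenitor cells at the base of the tracheal lining. The wild-type cells were isolated from the trachea and grown at an air-liquid interface, a culture in which cells on a porous membrane are fed from below and exposed to air above, so that they build a layered epithelium. Cells were collected on days 1, 3 and 5, which the submitters describe as stages of proliferation, stratification and luminal cell specification. Each day had 3 libraries, and the group and replicate number of all 9 came from the sample titles. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. No library was left out, and no column of values in the deposited table belonged to another sample.

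Libraries were made from total RNA with a VAHTS universal kit for Illumina, per the labels. Reads were aligned with HISAT2 2.1.0 to GRCm39 and normalized with DESeq2 1.36.0, per the submitters' processing notes. The read counter, the annotation release and whether strand was used in counting are not given in the sources used here. The authors deposited one table of log2 values per gene and library, and each value is the log2 of a read count divided by 1 size factor per library, with no pseudocount. A gene with no read has no log2 value, and 297330 such cells over the 56748 genes hold a spreadsheet error text, which was read as 0. The table had 57107 lines, of which 359 repeated a gene with the same values and were dropped. Returned to the linear scale, 100% of the values of each library were whole multiples of the value of 1 read, within 0.01 of a read, so whole reads and size factors were read back from the deposited values. Gene symbols and identifiers are those of the deposited table. No position is given, because the reference used here was another build, GRCm38 with GENCODE M21, which served only for transcript length, GC content, chromosome and overlap between genes by identifier; 98.3% of the tested genes had a length.

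Depth differed between days. The libraries held 16.4 to 35.1 M reads, and the means were 30.8 ± 4.29 M on day 1, 21.9 ± 2.55 M on day 3 and 17.6 ± 1.51 M on day 5 (SD, n = 3). Levels in the text are normalized counts, which is the deposited value on the linear scale. They are given as mean ± SD over the 3 libraries of a day unless stated otherwise.

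Genes with at least 10 normalized counts in at least 3 of the 9 libraries were tested, 17338 in all. The design fixed for log2 data was a test of the values as deposited. Because log2 of 0 is undefined, the test used log2(normalized count + 1), which understates the change of genes with few reads, and the deposited values without genes holding a 0 became an alternative. limma 3.58.1 in R 4.3.3 was fitted with 1 mean per day over all 9 libraries (lmFit, then eBayes with a mean-variance trend), which left 6 residual degrees of freedom. The comparisons were day 3 against day 1, day 5 against day 3 and day 5 against day 1. An F test covered any difference across the 3 days, and a contrast tested whether the step from day 3 to day 5 differed from the step from day 1 to day 3. All tests were two-sided, with Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a single gene in the text is from this limma fit unless another setting is named.

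The 32 gene lists, written before the data were examined, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. camera asks whether a list moved relative to the other genes. Of 926 list entries, 921 matched a gene of the table, 8 of them through an older symbol, and 5 did not match. The lists were basal cell; suprabasal and hillock; squamous cornification; luminal keratins and apical junctions; apicobasal polarity; secretory cell; multiciliated cell regulators; motile cilium structure; mitosis; DNA replication. Others covered cell cycle inhibitors and p53 targets, the Notch, Wnt, and BMP and TGF-beta pathways, YAP/TAZ targets, matrix adhesion and wound response, and epithelial-mesenchymal genes. Rare cell types were covered by ionocyte, tuft cell and neuroendocrine cell lists. The remaining lists were interferon response, inflammatory cytokines, glycolysis and hypoxia, cholesterol synthesis, retinoid response, glutathione and xenobiotic enzymes, ion channels, the mitochondrial genome, and immediate early and heat shock genes. Fibroblast, leukocyte, and endothelial, muscle and cartilage lists stood for other cell types of the trachea. Counts of list members that rose or fell use the adjustment over all tested genes, with the count adjusted over the list alone beside them.

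The genes named in the text follow a rule also written before the data were examined. It takes 12 genes whatever their result, the 6 largest rises and 6 largest falls per comparison among genes of at least 100 normalized counts whose libraries do not overlap between the days, and up to 3 called and 2 uncalled members of each list. Members that moved against the rest of a list, the genes behind the sex-linked and ribosomal protein values, and untested marker genes were named after their values were seen. A gene without reads in 1 day is given a lower bound of its fold, against a floor of 3 reads over the 3 libraries of that day. With 1 to 3 reads, the ratio of normalized reads is given with its exact 95% Poisson interval. Floors and intervals cover counting error only. Results of some genes under this rule are not reported.

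The code was tested on simulated data in which 100 genes were changed by 2-fold and 100 by 4-fold among 17338. For day 1 against day 3, 89% of the 2-fold and 97% of the 4-fold changes were recovered, for day 3 against day 5 83% and 100%, and for day 1 against day 5 89% and 96%. Each simulated comparison had 8 false calls, and no changed gene was called in the wrong direction. The simulation changed few genes, drew genes independently, used known size factors and held no trend on transcript length. These rates therefore check the code and need not hold for the real data.

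Alternatives listed before the data were examined were the replicate number as a block, no filter beyond 1 library with a read, a mean of at least 50 normalized counts, a pseudocount of 8, quantile normalization, TMM factors, no mean-variance trend, only the 2 days compared, leaving out each of the 9 libraries, and for lists an estimated correlation between genes and limma's fry. 5 alternatives were added after seeing the data. They were voom on the whole reads, the deposited log2 values without genes holding a 0, leaving out X- and Y-linked genes, removing each library's trend on transcript length and GC content (lowess, span 0.3), and leaving out genes that share exonic sequence with another gene together with pseudogenes. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

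Because groups hold 3 libraries, no test for a library far from the others of its group was run. Reads in a stretch covered by 2 genes may be counted for neither or for either, so a gene is called uncertain where its last 500 transcript bases or much of its exonic sequence lie over a neighbour's exons.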

Results

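RNA sequencing followed mouse tracheal basal cells over the first days at the air-liquid interface, with 3 libraries on each of days 1, 3 and 5. Totals ran from 16.4 to 35.1 M reads per library. A first principal component took 61.0% of the variance and ordered the libraries by day, and a second took 31.3% and set day 3 apart from both other days. Libraries of the same day correlated at 0.968 to 0.989 (Pearson's r of log2 values across genes, which are not independent replicates) and libraries of different days at 0.761 to 0.893. Replicates of a day differed by more than counting noise in every pair. Of 17338 tested genes, 15851 (91.4%) differed across the 3 days in the limma F test, and the following comparisons describe which.

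The 12 genes fixed in advance trace the main cell states, and the deposited table gives their identifiers. Basal cells were followed by Krt5 (ENSMUSG00000061527) and Krt14 (ENSMUSG00000045545), the keratin pair of the basal layer, and by Trp63 (ENSMUSG00000022510), the transcription factor that maintains basal identity. Krt8 (ENSMUSG00000049382) marks luminal and transitional cells, and Krt4 (ENSMUSG00000059668) and Krt13 (ENSMUSG00000044041) mark suprabasal and hillock cells. Scgb1a1 (ENSMUSG00000024653) and Scgb3a2 (ENSMUSG00000038791) encode secretoglobins of club cells, Foxj1 (ENSMUSG00000034227) the master regulator of motile cilia and Gmnc (ENSMUSG00000068428) the upstream switch of multiciliated fate. Mki67 (ENSMUSG00000031004) marks cycling cells, and Notch3 (ENSMUSG00000038146) is a Notch receptor of suprabasal cells.

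**Figure D1:**
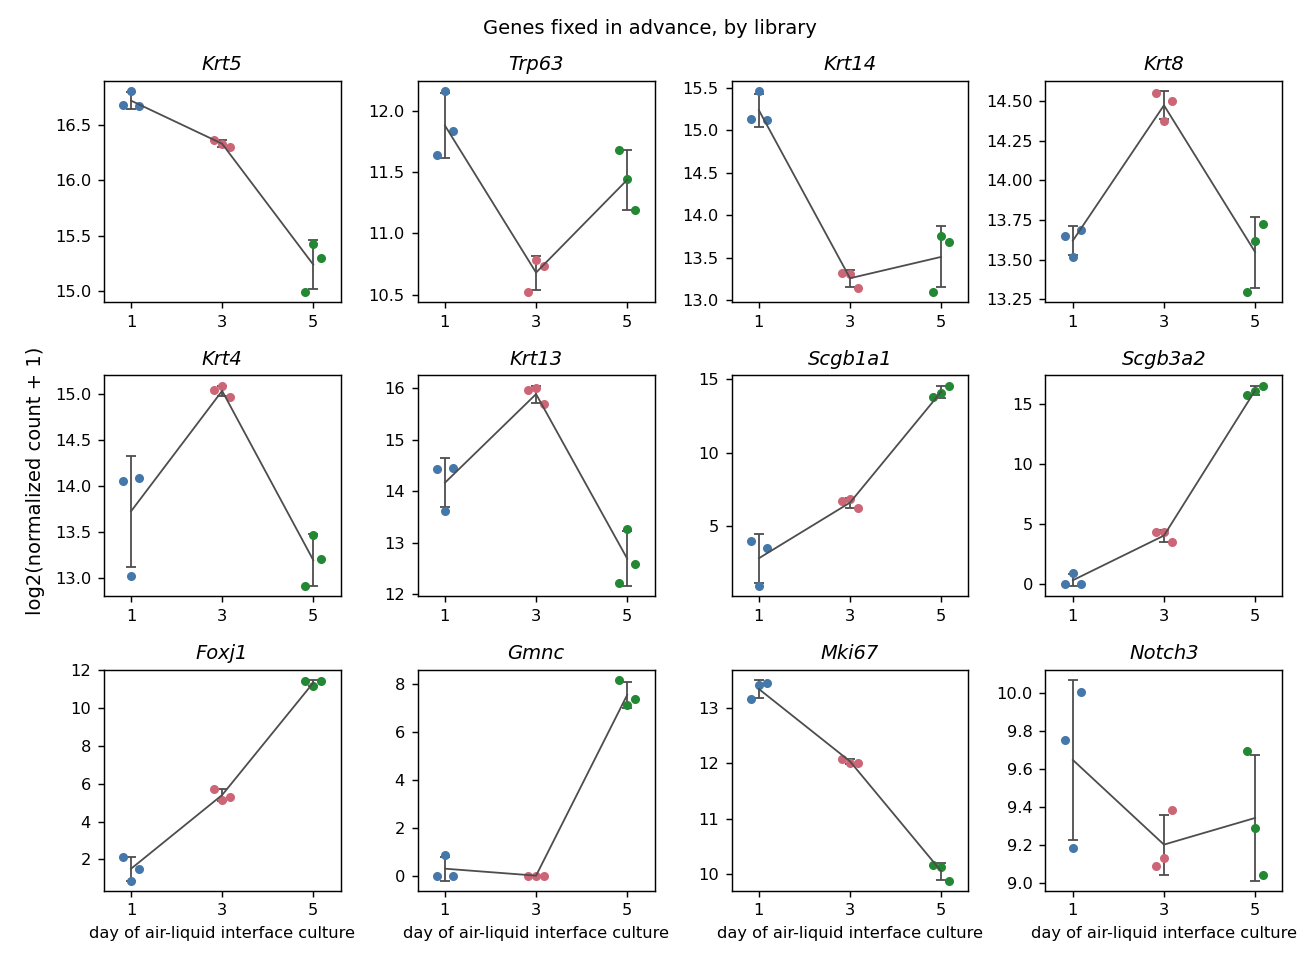
Log2(normalized count + 1) of the 12 genes fixed in advance against the day of culture; points are libraries (3 per day), lines join day means and bars are SDs. Krt8, Krt4 and Krt13 peak on day 3, Trp63 is lowest there, and Gmnc is near 0 until day 5.

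The step from day 1 to day 3 asks what changes as the cells leave the stage the submitters describe as proliferation and enter stratification. Most secretory, xenobiotic-metabolizing and interferon-response genes rose, and most genes of mitosis, cholesterol synthesis, matrix adhesion and cornification fell. As lists these passed camera, but 0 of 32 lists passed with an estimated correlation (adjusted p = 0.31 to 0.64 for the lists that camera passed; 4 of 32 at an unadjusted p under 0.05, and 25 passed fry). Interferon-response genes had 42 of 44 tested members up and a median log2 change of 3.96. Basal keratin Krt14 fell from 38820 ± 5429 to 9822 ± 663 normalized counts, and hillock keratin Krt13 rose from 19014 ± 5611 to 60955 ± 6808.

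Among secretory cell genes, 31 of 36 rose and 1 fell, with a median log2 change of 3.12, and the counts adjusted over the list alone were the same (limma camera, adjusted p = 1.6e-08; adjusted p = 0.44 with an estimated correlation). Lcn2, an antibacterial protein that binds siderophores, rose from 59.2 ± 43.4 to 4668 ± 817, and Pigr, the receptor that carries antibodies across epithelium, from 14.8 ± 5.10 to 1551 ± 444. Cbr2, a carbonyl reductase abundant in airway cells, rose from 4868 ± 2412 to 311058 ± 62847. The gel-forming mucin Muc5ac was the member that fell. Club cell Scgb1a1 was still at 96.8 ± 21.2 on day 3, up from 8.69 ± 7.18 (log2 change 3.80, SE 0.64, adjusted p = 3.1e-04). Scgb3a2 had 1 read on day 1 and a mean of 15.8 ± 5.12 on day 3, a ratio of 65.9 (95% counting interval 11.8 to 2604). Nkx2-1, the lung lineage factor, stood at 935 ± 167 and 1112 ± 116 (log2 change 0.26, adjusted p = 0.12).

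Glutathione and xenobiotic enzymes went the same way, with 27 of 37 up, 6 down and a median of 2.36, also when adjusted over the list alone (camera adjusted p = 9.3e-06; adjusted p = 0.44 with an estimated correlation). Cyp2a5, a cytochrome P450 that metabolizes nicotine and coumarin, rose from 3.27 ± 3.40 to 711 ± 184, and Ces1d, a carboxylesterase, from 134 ± 96.4 to 7504 ± 1444. Retinoid genes did not pass as a list (12 of 20 up, 5 down, camera adjusted p = 0.079; 0.045 with quantile normalization), but single members did. Dhrs3, which reduces retinal back to retinol, rose from 206 ± 5.46 to 9991 ± 1364 (log2 change 5.58, adjusted p = 1.3e-08). Adh1, an alcohol dehydrogenase that also oxidizes retinol, was among the 6 largest rises of the comparison, with a log2 change of 7.46.

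Interferon-response genes rose in 42 of 44 cases, 43 when adjusted over the list alone, and 1 fell (camera adjusted p = 1.1e-14; adjusted p = 0.31 with an estimated correlation). Ifit1, which binds foreign RNA ends, rose by a log2 change of 6.23, and Ifi44, a GTP-binding member of the response, rose from 1.03 ± 1.25 to 189 ± 23.7. Ifi27l2a went from 1 read to 157 ± 45.4, a ratio of 656 (118 to 25902). Ifitm1, which restricts virus entry, was also among the largest rises, from 33.5 ± 19.3 to 3976 ± 1085. Ifit2 fell. Inflammatory cytokines and chemokines had 18 of 29 up and 7 down, a median of 0.76, the same over the list alone (camera adjusted p = 0.030; adjusted p = 0.64 with an estimated correlation). Cd14, the co-receptor for bacterial lipopolysaccharide, rose from 539 ± 158 to 9214 ± 793, and the mucosal chemokine Cxcl17 from 43.1 ± 15.7 to 814 ± 162. This list no longer passed in a fit of only days 1 and 3 (adjusted p = 0.057) or without day 3 replicate 3 (adjusted p = 0.055).

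Markers of leukocytes moved beside these groups. Only 7 of 24 matched members were tested. Of these, 5 rose and none fell, the same over the list alone (camera adjusted p = 0.020; adjusted p = 0.31 with an estimated correlation). Lyz2, Itgam and Cd74 averaged 0.452, 3.73 and 4.18 on day 1. They could pass the filter mainly by being high on a later day, so the count of rises follows in part from the filter. Lyz2, a lysozyme of myeloid cells that airway and alveolar epithelium also makes, went from 2 reads to 550 ± 120, a ratio of 1163 (322 to 9602). Cd68, a lysosomal protein of macrophages, rose by a log2 change of 2.63 and Cd74 from 4.18 ± 1.27 to 33.2 ± 10.7. Ptprc, the pan-leukocyte antigen, and Tyrobp, a myeloid adaptor, had no read on day 3, and no untested member of the list averaged above 13.2 on any day. The list did not pass without a filter on low counts (adjusted p = 0.073) or on the deposited log2 values without genes holding a 0 (adjusted p = 0.11).

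Proliferation genes fell unevenly. In the mitosis list, 30 of 36 fell and Ccnb2, Cenpa and Pttg1 rose, with a median of −1.28 and the same counts over the list alone (camera adjusted p = 9.9e-07; adjusted p = 0.44 with an estimated correlation). Mki67 fell from 10441 ± 1149 to 4207 ± 128 (log2 change −1.31, adjusted p = 2.9e-06), but with the transcript length and GC trend removed its change was 0.04 (adjusted p = 0.74). Knl1, a kinetochore scaffold, fell from 1438 ± 139 to 147 ± 17.0. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, stood at 4051 ± 328 and 4036 ± 207 (adjusted p = 0.99). Of DNA replication genes, 24 of 40 fell, 25 over the list alone, and 7 rose, with a median of −0.55 (camera adjusted p = 3.5e-03; adjusted p = 0.64 with an estimated correlation). Orc1, of the origin recognition complex, fell by 2.68 on the log2 scale, while Pcna, the replication clamp, stood at 4369 ± 392 and 4168 ± 68.8 (adjusted p = 0.61).

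Cholesterol synthesis genes fell in 19 of 25 cases and Pmvk alone rose, with a median of −1.15, the same over the list alone (camera adjusted p = 4.2e-05; adjusted p = 0.31 with an estimated correlation). Hsd17b7, a sterol reductase of the pathway, fell from 2312 ± 134 to 235 ± 21.7 and Lss, the synthase that closes the sterol rings, from 5170 ± 248 to 923 ± 116. Matrix adhesion and wound genes fell in 26 of 38 cases and rose in 5 (Itgb5, Itgb6, Col7a1, Serpine2 and Timp1), with a median of −1.41, the same over the list alone (camera adjusted p = 9.7e-05; adjusted p = 0.52 with an estimated correlation). Epgn, a ligand of the EGF receptor, fell from 151 ± 23.4 to 5.18 ± 1.16, and Fst, the activin antagonist follistatin, from 2662 ± 555 to 112 ± 37.2. YAP/TAZ targets fell in 17 of 25 cases and Ccn2 rose, with a median of −0.77, the same over the list alone (camera adjusted p = 1.2e-03; adjusted p = 0.44 with an estimated correlation). Tead1, the DNA-binding partner of YAP, fell from 6067 ± 739 to 1283 ± 150.

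Of squamous cornification genes 12 of 16 fell and the keratins Krt1 and Krt10 rose, with a median of −2.35, the same over the list alone (camera adjusted p = 8.3e-03; adjusted p = 0.31 with an estimated correlation). Krt6b, a stress keratin, fell from 6993 ± 1140 to 177 ± 96.7 and its partner Krt16 from 2544 ± 665 to 149 ± 34.0. Apicobasal polarity genes fell in 14 of 18 cases and Pard6a, Prkcz and Crb3 rose, with a median of −0.63, the same over the list alone (camera adjusted p = 0.024; adjusted p = 0.62 with an estimated correlation). That call was lost with the length and GC trend removed (adjusted p = 0.15). Prkci, an atypical protein kinase C of the apical complex, fell from 5256 ± 530 to 1249 ± 111.

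Trp63 fell from 3811 ± 704 to 1644 ± 155 (log2 change −1.20, SE 0.15, adjusted p = 4.7e-05), with all libraries of day 3 below all of day 1, but with the length and GC trend removed the change was −0.22 (adjusted p = 0.090). Krt14 fell by 1.98 on the log2 scale (adjusted p = 4.2e-06). Krt5 stood at 108199 ± 5696 and 82486 ± 1709, and its change of −0.39 passed only narrowly (adjusted p = 0.0498). It did not pass with a pseudocount of 8 (adjusted p = 0.052), with TMM factors (adjusted p = 0.079) or in 8 of the 9 fits that left out a library, which kept the call only without day 5 replicate 1, but the fall was larger, and passed, with quantile normalization and with the length and GC trend removed (−1.04). Krt8 rose from 12601 ± 771 to 22813 ± 1403 (log2 change 0.86, adjusted p = 1.3e-04), a change of 0.08 with the length and GC trend removed (adjusted p = 0.45) and 0.39 with quantile normalization. Krt4 rose from 14272 ± 5143 to 33514 ± 1338 (log2 change 1.31, adjusted p = 8.7e-04; 0.66 and adjusted p = 0.081 with quantile normalization, 0.75 with the length and GC trend removed), and Krt13 rose by a log2 change of 1.72 (adjusted p = 2.5e-04; 1.05 and 0.96 under these 2 alternatives), while the suprabasal and hillock list as a whole had 8 of 20 up and 10 down with a median of −0.39 (camera adjusted p = 0.55). Basal cell genes as a list had 12 of 19 down and Krt15, Ngfr, Dapl1, Aqp3 and Sox15 up (camera adjusted p = 0.13). The list passed as lower with the length and GC trend removed (adjusted p = 0.015) and with quantile normalization (adjusted p = 0.038). Itga6, an integrin that anchors basal cells, fell from 21556 ± 2896 to 4130 ± 678.

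Foxj1 rose from 2.01 ± 1.29 to 41.9 ± 9.31 (log2 change 3.90, adjusted p = 2.25e-06; 2.31 with a pseudocount of 8), and Rsph9, a radial spoke protein, from 3.90 ± 1.09 to 59.1 ± 12.3. Of motile cilium genes 20 of 56 rose and Dnah10 and Tubb4b fell, with a median of 0.39, or 0.69 with genes lacking reads in 1 day set at their bound (camera adjusted p = 0.057, not passed). It passed with quantile normalization (adjusted p = 0.045) and on the deposited log2 values without genes holding a 0 (adjusted p = 2.7e-03), among other alternatives. Gmnc had 1 read on day 1 and none on day 3, so no fold is given. Notch3 stood at 824 ± 226 and 591 ± 66.5 (log2 change −0.45, adjusted p = 0.085), and passed only without day 1 replicate 2 (−0.68, adjusted p = 0.010).

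Several measured differences between the libraries ran alongside these groups. The summed Y-linked transcripts Ddx3y, Eif2s3y, Uty and Kdm5d stood at 3137 ± 113 normalized counts on day 1, 324 ± 24.2 on day 3 and 461 ± 98.3 on day 5, and Xist, transcribed from the inactive X, at 1825 ± 246, 5998 ± 507 and 7373 ± 1292. Every gene group that differs between day 1 and a later day therefore differs between libraries with unlike sex-linked transcripts. Transcript length ran with the change as well. Medians of log2 change from day 1 to day 3 went from 0.66 in the bin of the shortest transcripts to −0.76 in that of the longest. Ribosomal protein genes, which are short, took 5.28 ± 0.192%, 12.2 ± 1.42% and 5.90 ± 1.28% of reads on days 1, 3 and 5. With the length and GC trend removed, list medians were 3.95 for interferon response, 2.84 for secretory cell, −0.85 for mitosis and −0.90 for cholesterol synthesis. The basal cell list moved from −1.20 to −0.53, apicobasal polarity from −0.63 to −0.29, and immediate early and heat shock from 0.64 to −0.01.

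**Figure D2:**
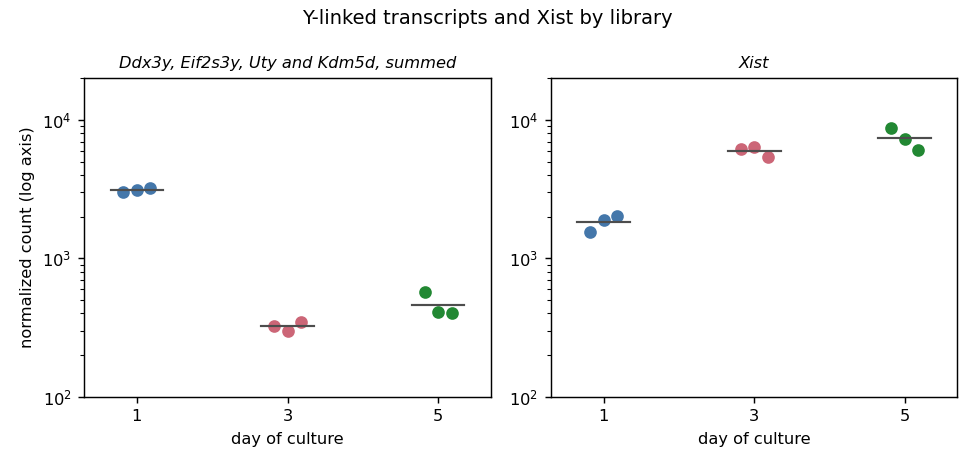
Normalized counts on a log axis of 4 summed Y-linked genes and of Xist against the day of culture; points are libraries (3 per day) and bars are means. The Y-linked sum lies at 3027 or above in the libraries of day 1 and at 575 or below in those of days 3 and 5.

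The largest falls of this step hold an uncertain class. Of the 6, Vcl (vinculin, which ties integrins to actin; 3065 ± 395 to 25.9 ± 17.0), Usp33 (758 ± 50.5 to 6.36 ± 6.41) and Sacm1l (814 ± 43.0 to 5.93 ± 3.11) have their last 500 bases wholly under exons of an opposite-strand neighbour. The gene called Zbed6 in the deposited data (1881 ± 387 to 8.51 ± 6.73) is named Gm38394 in the reference used here. There it shares 91.8% of its exonic bases with a same-strand entry that itself carries the name Zbed6. This overlap need not hold in the annotation used for counting. Tubb3, a beta-tubulin best known from neurons, fell from 1266 ± 491 to 3.05 ± 4.24, and Mroh6 from 347 ± 32.0 to 1.52 ± 0.395, without such overlap. Among 456 genes with at least 80% of their last 500 bases so covered, the median change was −0.94 and 61.2% fell. These values were −0.08 and 40.1% for 9177 genes without shared exonic bases. Both groups held only genes with a transcript of at least 1000 bases. The called list members Prc1, Kif20a, Fen1, Ccne2, Notch1, Rbl2, Fstl3 and Fosl1 belong to the covered class or nearly so, and their falls are uncertain.

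**Figure D3:**
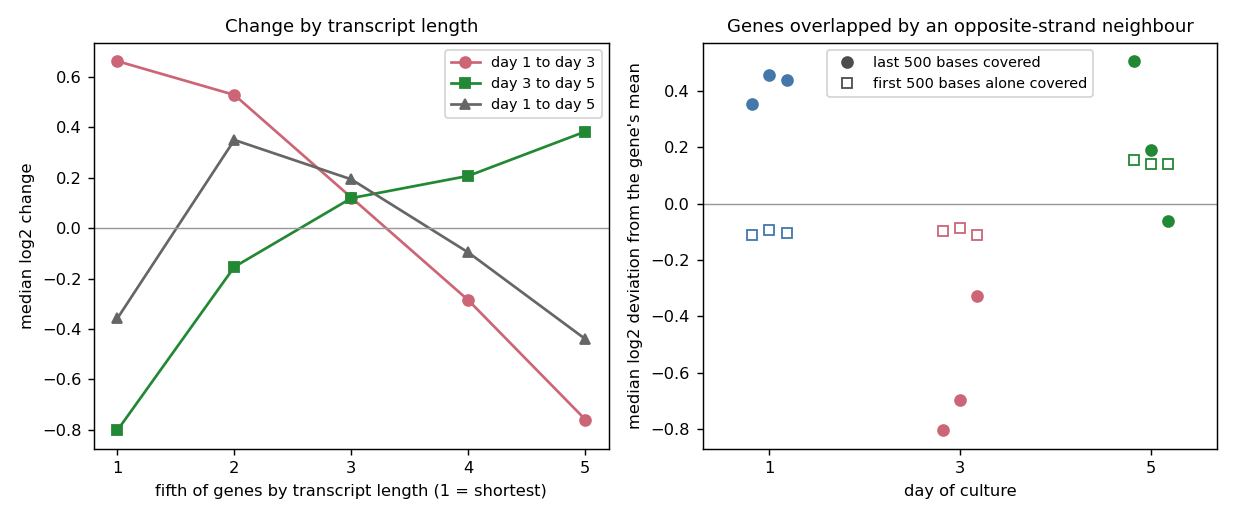
Left, median log2 change of genes by bin of transcript length, 1 line per comparison; right, median log2 deviation from each gene's mean for genes whose last (filled) or first alone (open) 500 bases lie at least 80% under an opposite-strand neighbour, 1 point per library against day. The shortest genes stand at 0.66 from day 1 to day 3 and at −0.80 from day 3 to day 5, and the genes covered at the last end are lowest on day 3.

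The other lists did not pass for this step. Luminal keratins and apical junctions had 13 of 26 up and 11 down (camera adjusted p = 0.74), with the claudins going both ways. Cldn3 rose from 2059 ± 272 to 12064 ± 1115 and Cldn1 fell from 823 ± 53.5 to 58.5 ± 22.0. In the suprabasal list, members went both ways, with Tgm2, a retinoid-induced transglutaminase, up from 176 ± 60.7 to 4886 ± 1243 and the cornified envelope protein Sprr3 down from 798 ± 189 to 25.5 ± 3.54. Notch genes had 10 of 29 up and 14 down (adjusted p = 0.74), with the target Hey1 up from 20.8 ± 6.33 to 388 ± 51.6. Glycolysis and hypoxia had 10 of 37 up and 21 down, 22 over the list alone (adjusted p = 0.079; 0.017 with quantile normalization and 0.020 with the length and GC trend removed). Wnt had 7 of 31 up and 15 down, ion channels 14 of 29 up, 15 over the list alone, and 10 down (both adjusted p = 0.30). Epithelial-mesenchymal genes had 2 of 11 up and 7 down (adjusted p = 0.079; 0.038 with the length and GC trend removed). Immediate early and heat shock genes had 17 of 33 up and 10 down (adjusted p = 0.44), with Fosb up from 467 ± 37.6 to 6666 ± 2583. Tuft cell genes had 8 of 16 up, 7 over the list alone, and 2 down (adjusted p = 0.25). Multiciliated regulators (8 of 29 up, 9 down), cell cycle inhibitors and p53 targets (11 of 24 up, 9 down, 10 over the list alone), ionocyte (5 of 13 up, 4 over the list alone, 3 down), endothelial, muscle and cartilage (2 of 6 up, 1 down) and mitochondrial genome genes (4 of 13 up, 6 down) all had an adjusted p of 0.74. Fibroblast (1 of 5 up, adjusted p = 0.80), BMP and TGF-beta (9 of 30 up, 10 down, adjusted p = 0.91) and neuroendocrine genes (3 of 11 up, 2 down, adjusted p = 0.94) completed the set. Median, mean and test direction differed in sign for 6 of these lists, namely BMP and TGF-beta, cell cycle inhibitors, fibroblast, multiciliated regulators, neuroendocrine and Notch.

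In all, 12665 of 17338 genes (73.0%) changed from day 1 to day 3 in the limma test, 6254 up and 6411 down, and 7997 of them by at least 2-fold. More genes rose than fell with TMM factors (6510 up, 6129 down) and with the length and GC trend removed (6473 up, 5869 down). Of the 32 lists, 12 passed camera, 0 passed with an estimated correlation (4 had an unadjusted p under 0.05), and 25 passed fry, which asks only whether the members move one way. Without genes that share exonic sequence and pseudogenes, 8068 of 11115 genes (72.6%) changed.

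The step from day 3 to day 5 covers the move to the stage the submitters describe as luminal specification. Most tested multiciliated, secretory, ionocyte, tuft and neuroendocrine genes rose, and most tested genes of proliferation, hillock cells, glycolysis and cholesterol synthesis fell. As lists these passed camera, and the motile cilium list alone also passed with an estimated correlation (adjusted p = 0.080 to 0.55 for the others that camera passed). Of 56 motile cilium genes 54 rose, with a median log2 change of 5.82. Club cell Scgb1a1 rose from 96.8 ± 21.2 to 18744 ± 5304 normalized counts, and Krt13 fell from 60955 ± 6808 to 6927 ± 2654.

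The motile cilium list had no member down and the same counts over the list alone (camera adjusted p = 2.4e-19), and it was the one list that kept its call with an estimated correlation (adjusted p = 9.2e-03). With genes lacking reads in 1 day at their bound, its median was 5.79, and on the deposited log2 values without genes holding a 0 it was 3.21 (adjusted p = 3.1e-09). Dnah5, an outer dynein arm heavy chain, had no read on day 3 and 404 ± 117 normalized counts on day 5, at least 345-fold higher. Tekt1, a tektin inside the ciliary doublets, was at least 302-fold higher at 354 ± 46.3, and Cfap65, an axonemal protein, at least 671-fold higher at 786 ± 203. Lrrc23, of the radial spoke, went from 2 reads to 1846 ± 141, a ratio of 2361 (654 to 19497). The tubulins Tubb4b (10571 ± 936 and 10487 ± 1001, adjusted p = 0.93) and Tuba1a (5690 ± 519 and 4908 ± 1004, adjusted p = 0.23) did not pass.

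Multiciliated cell regulators rose in 20 of 29 cases and E2f4, E2f7 and Plk3 fell, with a median of 1.51, the same over the list alone (camera adjusted p = 2.5e-05; adjusted p = 0.23 with an estimated correlation). The median was 0.96 with the length and GC trend removed and 0.42 on the deposited log2 values without genes holding a 0 (adjusted p = 0.029). Foxj1 rose from 41.9 ± 9.31 to 2594 ± 262 (log2 change 5.93, SE 0.31, adjusted p = 2.2e-07). Gmnc went from no read to 196 ± 80.3, at least 167-fold higher, and Deup1, of the deuterosome that mass-produces centrioles, to 512 ± 117, at least 437-fold higher.

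Secretory cell genes rose in 22 of 36 cases and fell in 8, with a median of 1.61, the same over the list alone (camera adjusted p = 1.6e-03; adjusted p = 0.55 with an estimated correlation). The call was lost on the deposited log2 values without genes holding a 0 (median 0.88, adjusted p = 0.12). Scgb3a2 rose from 15.8 ± 5.12 to 72296 ± 20039 (log2 change 12.09, adjusted p = 1.3e-08), Bpifa1, a surface-active secreted protein of the airway lining, from 34.0 ± 2.51 to 125696 ± 20475, and Reg3g, an antibacterial lectin, by a log2 change of 8.41. Cbr2 stayed high at 311058 ± 62847 and 311624 ± 63373 (log2 change 0.00, SE 0.39). Xenobiotic enzymes had 22 of 37 up and 12 down (camera adjusted p = 0.095, not passed), though the list passed as higher with the length and GC trend removed (adjusted p = 0.014) and with quantile normalization (adjusted p = 7.6e-03). Sult1d1, a sulfotransferase, rose from 35.5 ± 9.18 to 5336 ± 909. Pon1, a paraoxonase, and Sec14l3, a lipid-binding protein of airway epithelium, were also among the largest rises, from 2.44 ± 2.71 to 2408 ± 260 and from 4.97 ± 2.61 to 3694 ± 1448.

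Neuroendocrine genes rose in 9 of 11 cases with none down and a median of 5.29 (camera adjusted p = 3.3e-04), ionocyte genes in 9 of 13 with none down and a median of 1.94 (7.7e-04), and tuft cell genes in 12 of 16 with Alox5ap down and a median of 3.05 (1.6e-03). The counts over the list alone were the same, and each list had an adjusted p = 0.080 with an estimated correlation. Only 11 of 18 matched neuroendocrine genes were tested, with median counts of 1.03, 1.25 and 51.9 on days 1, 3 and 5. For tuft cell genes these were 16 of 20, with 2.11, 9.05 and 42.4. Members this low on days 1 and 3 could pass the filter mainly by being high on day 5, so the counts of rises follow in part from the filter. With a pseudocount of 8, the neuroendocrine median was 2.83 and the tuft cell median 1.95. On the deposited log2 values without genes holding a 0, the ionocyte median was 1.02 (adjusted p = 0.046) and the tuft cell median 1.95 (adjusted p = 0.046). The neuroendocrine granule protein Chga went from 1 read to 107 ± 10.6, a ratio of 270 (48.5 to 10674). Foxi1, which specifies ionocytes, went from 1 read to 154 ± 10.3, a ratio of 394 (70.6 to 15544), and Atp6v1b1, a proton pump subunit, rose from 2.62 ± 1.35 to 269 ± 27.4. Trpm5, the taste-signalling channel of tuft cells, rose from 3.27 ± 3.66 to 147 ± 20.4.

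Suprabasal and hillock genes fell in 16 of 20 cases, 17 over the list alone, and Tgm2 rose, with a median of −1.85 (camera adjusted p = 1.0e-05; adjusted p = 0.23 with an estimated correlation). Krt13 fell by 3.20 on the log2 scale (SE 0.28, adjusted p = 5.8e-06) and Krt4 by 1.84 (adjusted p = 1.3e-04; −0.97 and adjusted p = 0.020 with quantile normalization). Sprr1a, of the cornified envelope, fell from 2687 ± 722 to 40.2 ± 3.57, and Ivl, involucrin, also fell (log2 change −4.22). Klk13, a kallikrein protease, fell from 908 ± 207 to 9.45 ± 2.21. Sprr2b fell to 1 read, a ratio of day 3 over day 5 of 1106 (199 to 43691). Squamous genes had 4 of 16 up (Krt1, Flg, Scel and Rptn) and 8 down (camera adjusted p = 0.21). Krt8 fell from 22813 ± 1403 to 12066 ± 1809 (log2 change −0.93, adjusted p = 1.2e-04), which did not pass with quantile normalization (−0.21, adjusted p = 0.13), and luminal keratins and junctions had 12 of 26 down and 5 up (camera adjusted p = 0.077; 7.1e-03 with the length and GC trend removed). Krt7 fell from 116872 ± 7705 to 16155 ± 2678.

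In the basal layer, Krt5 fell from 82486 ± 1709 to 38922 ± 5823 (log2 change −1.09, adjusted p = 2.0e-04; −0.45 with quantile normalization). Trp63 rose from 1644 ± 155 to 2798 ± 472 (log2 change 0.76, adjusted p = 1.6e-03), with all libraries of day 5 above all of day 3, but the change was 0.27 (adjusted p = 0.044) with the length and GC trend removed. Krt14 stood at 9822 ± 663 and 11899 ± 2728 (log2 change 0.25, adjusted p = 0.23), and passed only with quantile normalization (0.75), with the length and GC trend removed (0.49) or without day 5 replicate 1 (0.46). Basal genes as a list had 7 of 19 up and 7 down (camera adjusted p = 0.82). Notch3 stood at 591 ± 66.5 and 660 ± 154 (adjusted p = 0.58).

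Proliferation fell further. DNA replication genes fell in 37 of 40 cases and Ccne2 rose (median −1.98, camera adjusted p = 4.5e-16), and mitosis genes in 33 of 36 with Kif20a up, 2 up over the list alone (median −1.68, adjusted p = 4.6e-14). Ccne2 and Kif20a are of the covered class above, and both lists had an adjusted p = 0.16 with an estimated correlation. Mki67 fell from 4207 ± 128 to 1068 ± 108 (log2 change −1.98, adjusted p = 2.8e-07), Ube2c from 4036 ± 207 to 549 ± 89.7, and Gins1, of the replicative helicase, from 445 ± 12.7 to 64.8 ± 21.3. Glycolysis and hypoxia genes fell in 23 of 37 cases, 24 over the list alone, and rose in 6 (median −0.74, camera adjusted p = 7.7e-04; −0.32 and adjusted p = 0.041 with quantile normalization; adjusted p = 0.16 with an estimated correlation). Slc16a3, a lactate exporter, fell from 613 ± 72.6 to 124 ± 3.04. Cholesterol synthesis genes fell in 20 of 25 cases with none up (median −0.50, camera adjusted p = 5.6e-06; −0.82 with the length and GC trend removed; adjusted p = 0.089 with an estimated correlation). Pmvk, a kinase of the mevalonate pathway, fell from 2347 ± 241 to 656 ± 132. Matrix adhesion genes fell in 21 of 38 cases and 4 rose, among them Col7a1, Mmp13 and Thbs1 (median −0.68, camera adjusted p = 2.2e-03; −0.32 and adjusted p = 0.027 with quantile normalization; adjusted p = 0.55 with an estimated correlation). Col4a1, a basement membrane collagen, fell from 372 ± 78.9 to 28.5 ± 4.56. The counts of these lists were otherwise the same over the list alone.

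Notch genes rose in 17 of 29 cases and Nrarp and Adam10 fell (median 0.40, camera adjusted p = 5.2e-03; 0.64 with quantile normalization; adjusted p = 0.30 with an estimated correlation), a call lost with the length and GC trend removed (adjusted p = 0.091). The ligand Dll3 rose from 1.52 ± 0.395 to 21.4 ± 3.91 and Dll4 from 7.60 ± 4.42 to 35.3 ± 8.58. Wnt genes rose in 19 of 31 cases and Tcf7, Wnt7a, Wnt7b, Wnt9a and Wnt10a fell (median 0.77, camera adjusted p = 0.019; 0.40, 15 up, 8 down and adjusted p = 0.049 with the length and GC trend removed; adjusted p = 0.29 with an estimated correlation), a call that narrowly failed on the deposited log2 values without genes holding a 0 (adjusted p = 0.052). Lgr6, a receptor for R-spondins, rose from 1.73 ± 2.02 to 857 ± 71.2 and Wnt5b from 6.73 ± 1.14 to 240 ± 32.0. Both lists had the same counts over the list alone.

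Interferon-response genes had 4 of 44 up, 10 down and 30 not passed, or 2 up and 6 down over the list alone (camera adjusted p = 0.19). H2-K1 of class I antigen presentation stood at 14656 ± 733 and 14813 ± 2611. Inflammatory genes had 9 of 29 up and 16 down (adjusted p = 0.17), with the alarmin Il33 down from 3850 ± 237 to 435 ± 74.5. Leukocyte markers had Lyz2 and Kit up and 4 of 7 down (adjusted p = 0.28). Lyz2 rose from 550 ± 120 to 70299 ± 9766, while Ly6g, a neutrophil marker in mice, fell from 128 ± 7.59 to no read, at least 111-fold lower. Fibroblast markers, of which only 5 of 20 matched were tested, had 3 of 5 up and 2 down (adjusted p = 0.47). The risers Dcn, Pi16 and Ogn could pass the filter mainly by being high on day 5. Dcn, the matrix proteoglycan decorin, went from no read to 112 ± 16.1, at least 95.9-fold higher, and Pi16 to 48.3 ± 4.95, at least 41.2-fold higher, while the fibroblast collagens Col1a1, Col1a2 and Col3a1 averaged 0.661, 0.410 and 0.430 on day 5. Reads of the mitochondrial genome took 2.74 ± 0.381% on day 3 and 6.23% on day 5, and its genes rose in 11 of 13 cases with none down (median 0.92, camera adjusted p = 5.3e-03; adjusted p = 0.22 with an estimated correlation; the same counts over the list alone).

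The remaining lists of this step did not pass. They were retinoid (10 of 20 up, 6 down, camera adjusted p = 0.65), BMP and TGF-beta (16 of 30 up, 11 down, 0.36), YAP/TAZ (11 of 25 up, 8 down, 0.79), cell cycle inhibitors and p53 targets (5 of 24 up, 12 down, 0.13), ion channels (13 of 29 up, 5 down, 0.20), immediate early and heat shock (12 of 33 up, 15 down, 0.82), epithelial-mesenchymal (4 of 11 up, 5 over the list alone, 5 down, 0.90), apicobasal polarity (5 of 18 up, 4 down, 0.99) and endothelial, muscle and cartilage genes (2 of 6 up, 2 down, 0.81). Aldh1a1, a retinal dehydrogenase, rose from 1595 ± 119 to 43710 ± 1567 (adjusted p = 1.9e-07), and Crabp1, which binds retinoic acid, fell from 239 ± 34.5 to 1.56 ± 1.91 (adjusted p = 1.4e-06). The immediate early list had a positive median and a negative mean and test direction.

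From day 3 to day 5, 11664 genes (67.3%) changed in the limma test, 6040 up and 5624 down, and 6488 by at least 2-fold. The balance turned with the length and GC trend removed (5355 up, 6166 down) and with quantile normalization (5603 up, 5785 down). Camera passed 15 of 32 lists, of which 1 passed with an estimated correlation (8 had an unadjusted p under 0.05), and fry passed 24. The length trend ran the other way, with medians from −0.80 in the bin of the shortest transcripts to 0.38 in that of the longest, and ribosomal protein genes fell in 80 of 81 cases (median −1.39).

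**Figure D4:**
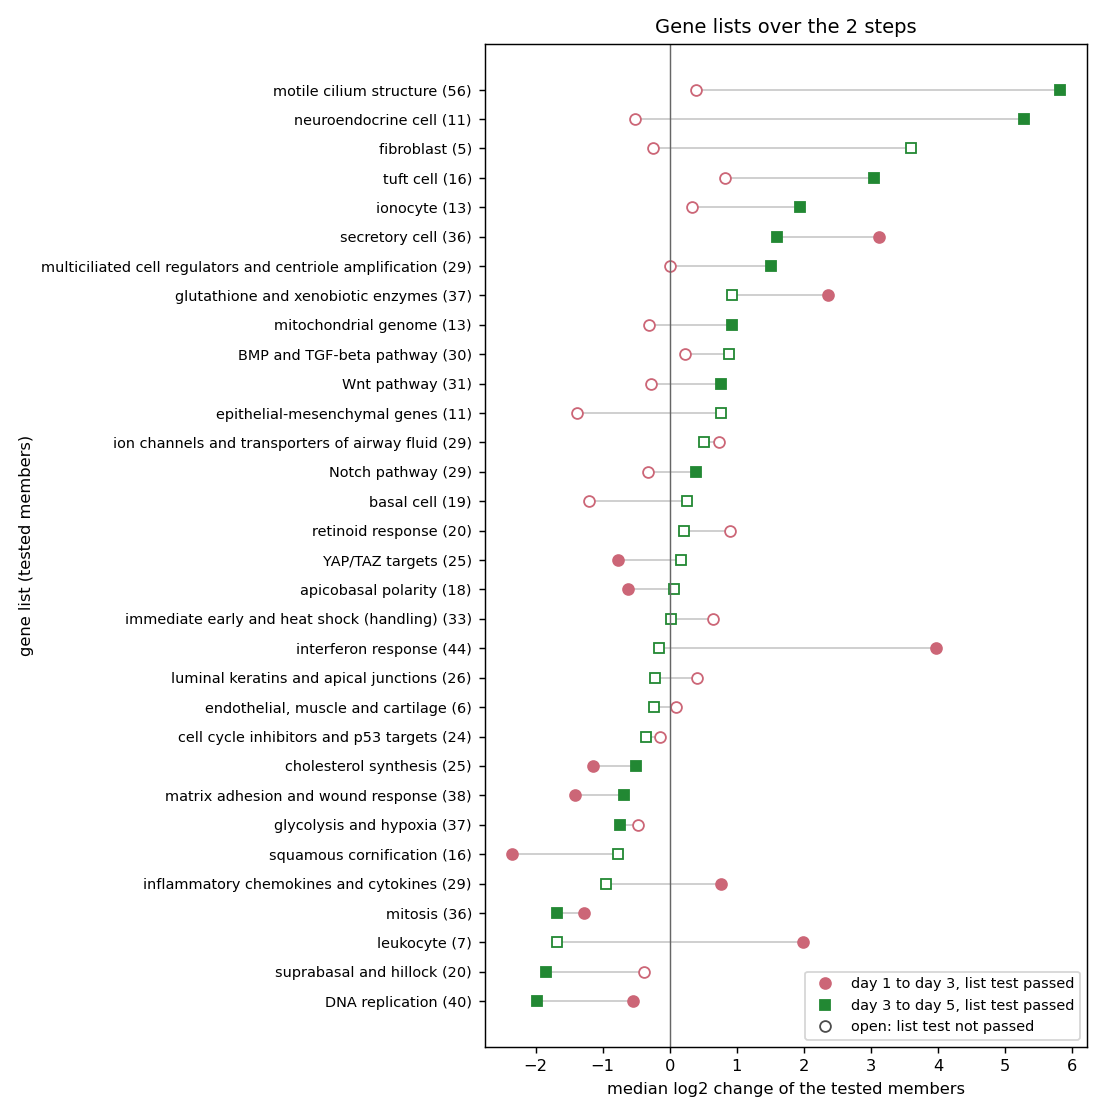
Median log2 change of the tested members of each gene list (number in brackets) from day 1 to day 3 (circles) and from day 3 to day 5 (squares), filled where the camera test passed. Motile cilium structure has the highest median of the later step (5.82) and interferon response that of the earlier (3.96).

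Day 5 against day 1 gives the net change over the course. Cells of day 5 had more cilium, secretory, rare cell and interferon transcripts and fewer of proliferation, matrix adhesion, cornification and cholesterol synthesis than cells of day 1. These lists passed camera, and with an estimated correlation the motile cilium list alone did (adjusted p = 0.052 to 0.48 for the others that camera passed). All 40 DNA replication genes fell (median −2.51), and 54 of 56 motile cilium genes rose (median 6.55). Bpifa1 and Scgb3a2, with 1 read each on day 1, stood above Krt5 on day 5.

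Motile cilium genes other than the tubulins Tubb4b and Tuba1a rose, the same over the list alone (camera adjusted p = 1.2e-16; adjusted p = 0.014 with an estimated correlation). Dynlrb2, a dynein light chain, went from no read to 425 ± 79.2, at least 613-fold higher, and Foxj1 from 2.01 ± 1.29 to 2594 ± 262 (log2 change 9.84, adjusted p = 4.1e-09). Gmnc went from 1 read to 196 ± 80.3, a ratio of 882 (158 to 34830). Multiciliated regulators had 18 of 29 up and 9 down (median 1.46, camera adjusted p = 0.020; adjusted p = 0.47 with an estimated correlation). That call was lost with a mean of at least 50 normalized counts, without genes sharing exons (adjusted p = 0.082), without day 5 replicate 1 (adjusted p = 0.061) and on the deposited log2 values without genes holding a 0 (median −0.27, adjusted p = 0.93), and the median was 2.21 with the length and GC trend removed. Secretory genes had 34 of 36 up and Galnt6 down (median 5.04, or 5.06 with genes at their bound; camera adjusted p = 1.5e-11; adjusted p = 0.21 with an estimated correlation). Bpifa1 went from 1 read to 125696 ± 20475 and Scgb3a2 from 1 read to 72296 ± 20039, ratios of 540815 (97066 to 21361000) and 307359 (55165 to 12140000). Scgb1a1 rose by a log2 change of 11.37 (adjusted p = 9.6e-08). Xenobiotic enzymes had 27 of 37 up, 28 over the list alone, and 6 down (median 2.41, camera adjusted p = 4.7e-06; adjusted p = 0.27 with an estimated correlation), and Cyp2a5 reached 40139 ± 3029 from 3.27 ± 3.40.

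Tuft cell genes had 13 of 16 up, 15 over the list alone (median 3.77, camera adjusted p = 9.3e-05; adjusted p = 0.052 with an estimated correlation), neuroendocrine genes 11 of 11 up (median 4.77, adjusted p = 1.7e-04; adjusted p = 0.057 with an estimated correlation), and ionocyte genes 9 of 13 up with P2ry14 and Ctnnal1 down (median 4.16, adjusted p = 0.013; adjusted p = 0.12 with an estimated correlation). The ionocyte call was lost with a mean of at least 50 normalized counts (adjusted p = 0.058) and on the deposited log2 values without genes holding a 0 (median 0.35, adjusted p = 0.56). With a pseudocount of 8 the medians of these 3 lists were 2.02, 2.77 and 1.75. The limit set by the filter on the neuroendocrine and tuft cell counts of the later step holds here too. Foxi1 went from no read to 154 ± 10.3, at least 222-fold higher. Cftr, the chloride channel enriched in ionocytes, stood at 42.3 ± 6.99 and 55.3 ± 18.3 (adjusted p = 0.37). Interferon genes stayed up, with 43 of 44 above day 1 and Ifit2 below (median 3.89, camera adjusted p = 9.6e-13; adjusted p = 0.17 with an estimated correlation), and Oasl2, an interferon-induced antiviral protein, at 15.8 ± 5.28 and 1051 ± 121.

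Mitosis genes had 35 of 36 down and Pttg1 up (median −2.87), and with DNA replication shared a camera adjusted p of 4.3e-15 and an adjusted p = 0.14 with an estimated correlation. Mki67 fell by 3.29 on the log2 scale (adjusted p = 5.1e-09) and Rrm2, a ribonucleotide reductase subunit, from 6331 ± 710 to 357 ± 32.5. Cholesterol synthesis genes had 23 of 25 down and none up (median −1.91, camera adjusted p = 1.8e-09; adjusted p = 0.052 with an estimated correlation), with Idi1 from 12585 ± 391 to 1605 ± 136. Matrix adhesion genes had 32 of 38 down and 4 up (camera adjusted p = 1.9e-07; adjusted p = 0.27 with an estimated correlation), with Krt6a, a wound keratin, from 33601 ± 2233 to 573 ± 35.8. Glycolysis had 25 of 37 down, 26 over the list alone, and 5 up (median −0.79, adjusted p = 1.7e-04; adjusted p = 0.12 with an estimated correlation). YAP/TAZ targets had 20 of 25 down and Ccn1, Ccn2, Rbms3 and F3 up (median −1.08, adjusted p = 2.1e-03; adjusted p = 0.34 with an estimated correlation). Suprabasal genes had 15 of 20 down and Tgm2 up (median −1.33, adjusted p = 1.6e-04; adjusted p = 0.27 with an estimated correlation), and squamous genes 12 of 16 down with Krt1 and Krt10 up (median −2.50, adjusted p = 2.0e-03; adjusted p = 0.11 with an estimated correlation). Sprr1b and Krtdap had no read on day 5, at least 147-fold and 133-fold lower, and Il24, a cytokine, fell from 783 ± 120 to 1.91 ± 0.588. Apicobasal polarity genes had 13 of 18 down, 14 over the list alone, and 2 up (median −0.64, adjusted p = 0.018; adjusted p = 0.48 with an estimated correlation), a call lost with quantile normalization (−0.37, adjusted p = 0.16), without genes sharing exons (adjusted p = 0.070) and with a mean of at least 50 normalized counts (adjusted p = 0.051).

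Krt5 fell by 1.48 on the log2 scale (adjusted p = 1.1e-05), Krt14 by 1.73 (adjusted p = 6.6e-06) and Krt13 by 1.48 (adjusted p = 6.9e-04). Trp63 changed by −0.44 (adjusted p = 0.024), with libraries of the days overlapping. That call was lost with quantile normalization (−0.03), without the mean-variance trend (adjusted p = 0.051) and without day 1 replicate 2 (−0.30), day 5 replicate 2 or day 5 replicate 3, and the change was 0.05 (adjusted p = 0.67) with the length and GC trend removed. Krt8 stood at 12601 ± 771 and 12066 ± 1809 (adjusted p = 0.62; −0.72 and adjusted p = 4.2e-05 with the length and GC trend removed), and Krt4 at 14272 ± 5143 and 9500 ± 1818 (−0.53, adjusted p = 0.084), which passed only without day 1 replicate 2 (−0.88) or with the length and GC trend removed (−1.04). Notch3 stood at 824 ± 226 and 660 ± 154 (adjusted p = 0.22), and passed only without day 1 replicate 2 (−0.54, adjusted p = 0.029).

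Lists that did not pass from day 1 to day 5 were basal cell (6 of 19 up, 12 down, camera adjusted p = 0.23), luminal keratins (7 of 26 up, 12 down, 0.27; 0.014 with the length and GC trend removed), retinoid (12 of 20 up, 5 down, 0.061), mitochondrial genome (10 of 13 up, mt-Atp8 down, 0.055; 0.014 with that trend removed), epithelial-mesenchymal (Vim up, 8 of 11 down, 0.055; 0.037 with that trend removed and 0.027 with quantile normalization), ion channels (17 of 29 up, 10 down, 0.092), Notch (15 of 29 up, 11 down, 0.31), Wnt (15 of 31 up, 8 down, 0.28), BMP and TGF-beta (13 of 30 up, 14 down, 0.82) and inflammatory genes (13 of 29 up, 12 down, 0.73). The same held for immediate early and heat shock (15 of 33 up, 16 down, 0.85), leukocyte (3 of 7 up, 3 down, 0.82), fibroblast (3 of 5 up, 2 down, 0.37), cell cycle inhibitors and p53 targets (8 of 24 up, 7 over the list alone, 8 down, 0.80), and endothelial, muscle and cartilage genes (3 of 6 up, 3 down, 0.99). Median, mean and test direction differed in sign for BMP and TGF-beta, cell cycle inhibitors, and immediate early genes. Where no other count is given, the counts of this comparison were the same over the list alone.

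From day 1 to day 5, 12909 genes (74.5%) changed in the limma test, 6367 up and 6542 down (6744 up and 6186 down with TMM factors), and 8544 by at least 2-fold. Camera passed 17 of 32 lists, of which 1 passed with an estimated correlation (9 had an unadjusted p under 0.05), and fry passed 30. Members of families with near-identical copies, among the genes above Sprr1, Sprr2, Cyp2a5, Lyz2 and the Ifit genes, can share reads, so their single values are uncertain.

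The 2 steps were also compared directly, by a contrast of the later step minus the earlier. Of interferon genes, 41 of 44 were lower in the later step (median −4.21, camera adjusted p = 3.6e-12; adjusted p = 0.34 with an estimated correlation), and 46 of 56 motile cilium genes were higher in it (median 5.22, adjusted p = 2.1e-08; adjusted p = 0.090 with an estimated correlation). Krt13 (difference −4.92), Krt4 (−3.14) and Krt8 (−1.78) were higher on day 3 than on either other day, and Trp63 (1.96; 0.48 with the length and GC trend removed) and Krt14 (2.23, adjusted p = 1.1e-04; 3.36 with that trend removed) had a lower earlier step than later one. Krt5 went the other way (−0.70, adjusted p = 0.044). Its difference was −0.01 (adjusted p = 0.98) with that trend removed and turned sign with quantile normalization (1.17, adjusted p = 7.1e-04). The contrast passed for 12264 of 17338 genes (70.7%), and 11 of 32 lists passed camera, 0 of them with an estimated correlation (4 had an unadjusted p under 0.05; fry passed 28).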

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

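The tests of another mix of male and female animals, of a library swap and of the terminal oligopyrimidine class below were chosen after the results were seen.

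The 2 steps of the course differed for 12264 genes by the direct contrast, and among the genes fixed in advance 4 moved in opposite directions in the 2 steps. Krt13 (difference of steps −4.92), Krt4 (−3.14) and Krt8 (−1.78) rose to day 3 and fell after it, while Trp63 (1.96) fell to day 3 and rose after it. With the length and GC trend removed, the first step was 0.08 for Krt8 (adjusted p = 0.45) and −0.22 for Trp63 (adjusted p = 0.090), the second was −0.80 and 0.27 (adjusted p = 0.044), and the difference of steps was −0.89 for Krt8 and 0.48 for Trp63 (adjusted p = 0.038). With quantile normalization the difference was −0.60 for Krt8 (adjusted p = 0.021) and −1.63 for Krt4. Under that setting the first step of Krt4 and the second step of Krt8 did not pass, so their opposite directions are not called there. In 100 splits of the 9 libraries, the real one included, 1 gave as many genes with a step difference as the real split, the real one itself. The highest other count was 4145. A random grouping of these libraries is argued against for that count, at no finer share than 1 of 100. The splits cannot tell the day of culture from other differences between the libraries of the days. The same holds for the F test, with 15851 genes in the real split, 8163 in the highest other and 1 of 100 as large.

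For 2 days at a time, the 6 libraries make 10 splits, too few for a share under 0.05. From day 1 to day 3 the real split gave 12713 changed genes and the highest other 0 (limma, with 394 genes at an unadjusted p under 0.05). From day 3 to day 5 these were 11233 and 0 (417 unadjusted), and from day 1 to day 5 12673 and 0 (135 unadjusted), so 1 of 10 splits was as large each time. For changes of at least 2-fold the real counts were 7900, 6384 and 8538, the highest other 0, and again 1 of 10 was as large. For gene lists the real counts were 11, 16 and 18, the highest others 14, 15 and 19, and 5, 1 and 4 of 10 splits gave as many.

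Sex-linked transcripts separated day 1 from the later days. The median log2 change of Ddx3y, Eif2s3y, Uty and Kdm5d from day 1 to day 3 was −3.57 (SD 0.42), and Xist rose by a log2 change of 1.72 (adjusted p = 3.0e-06), which is what another mix of male and female cells in the day 1 libraries may give. A swap of single libraries between days is argued against, because the lowest day 1 library held 5.27 times the Y-linked counts of the highest later library. The X- and Y-linked genes themselves are too few to make up the change, since 12241 genes changed without them. Whether autosomal differences between day 1 and later days also reflect animals of another sex stays open, because the labels give no sex and all day 1 libraries stand together.

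Ribosomal protein genes took a larger share of reads on day 3. Their 81 tested genes had a median log2 change of 1.54 from day 1 to day 3, with 77 higher. Other genes matched for transcript length and GC content had a median of 1.03 (99% of 1000 draws from 0.72 to 1.41), so a gain of short transcripts on day 3 may account for much of it. With the length and GC trend removed, 0.87 remained. Length was that of the longest annotated coding transcript, and the interval covers only the choice of matched genes. Whether transcript length accounts for all of the rise therefore cannot be decided. Size factors alone are argued against by a median of 0.95 or more under quantile and TMM scaling. In 15 other genes of the terminal oligopyrimidine class the median was 0.22 (spread 0.36), with 8 higher and 3 lower. These were not matched to the ribosomal protein genes for transcript length, so the test cannot decide on a rise of the whole class. The rest is open, and no biological explanation was tested beyond that class.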

How the results depend on the processing

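Each of 487 single-gene values was recomputed under the alternatives. Counted over values and alternatives other than leaving out a library, 5795 kept their side of the threshold, 178 passed newly and 18 lost their call. In 2 more, a called change turned sign. A turn of sign where neither fit passed was counted as kept, and the difference of the 2 steps was not part of these counts. For lists these were 1160, 43, 15 and 0, where the last counts only lists that passed in opposite directions. The list counts leave out the estimated correlation and fry, which are given below. Leaving out libraries kept 4304 gene results, with 62 newly passed and 17 lost, and 850 list results, with 12 and 2.

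With the length and GC trend removed, Mki67 from day 1 to day 3 was 0.042 (adjusted p = 0.74) and Trp63 from day 1 to day 5 was 0.052 (adjusted p = 0.67), against −1.31 and −0.44. The cause was not tested.

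With an estimated correlation between genes, 0, 1 and 1 lists passed, against 12, 15 and 17 with camera. The order is day 1 to day 3, day 3 to day 5 and day 1 to day 5. The setting replaced the preset correlation of 0.01 by an estimate per list, such as 0.376 for secretory cell and 0.333 for matrix adhesion genes. Tuft cell and ionocyte genes, at −0.046 and −0.012, lost their calls too, so a larger correlation alone does not account for this. From day 1 to day 5 their unadjusted camera p rose from 2.6e-05 to 4.1e-03 and from 5.9e-03 to 0.027. The rest of the cause was not tested. With fry, which tests members without the other genes as reference, 25, 24 and 30 passed. A mean of at least 50 normalized counts left 4039 genes changed by at least 2-fold from day 3 to day 5 and 5647 from day 1 to day 5, from fewer genes tested. Without genes that share exonic sequence and pseudogenes, 11115 genes were tested and the counts were lower for that reason. They were 8068 changed and 5179 by at least 2-fold from day 1 to day 3 (72.6% and 46.6% of the tested), 7474 and 4182 from day 3 to day 5 (67.2% and 37.6%), 8483 from day 1 to day 5 (76.3%), 10202 in the F test (91.8%) and 7789 for the step difference (70.1%).

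Counts of changed genes for the 3 comparisons in that order were 12690, 11426 and 13042 with voom, 12344, 11388 and 12957 with quantile normalization, 12639, 11702 and 12930 with TMM factors, and 12342, 11521 and 13182 with the length and GC trend removed. Per gene, the change with quantile normalization minus that of the main fit had a median of −0.12 from day 3 to day 5 and from day 1 to day 5. With the trend removed this median was −0.13 from day 3 to day 5. With the replicate number as a block the counts of changed genes were 12206, 10979 and 12437. Libraries with the same number correlated at −0.31 to 0.14 after removal of day means, and 2 of 9 libraries correlated best with their own number, so the numbers were not taken to pair samples. Without 1 library at a time, 11750 to 12963, 10273 to 11643 and 11962 to 13077 genes changed, 7651 to 8318, 5708 to 6861 and 8226 to 8727 by at least 2-fold, and 11 to 13, 15 to 16 and 16 to 20 lists passed. The F test gave 15274 to 15762 genes and the step difference 10775 to 12388.

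Mean size factors were 1.44, 0.854 and 0.865 on days 1, 3 and 5, so 1 read is a larger normalized count on days 3 and 5 than on day 1, and bounds for genes without reads are looser there.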

Other observations

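The test of mitochondrial transcription below was chosen after the result was seen.

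Some basal genes rose while Krt5 and Krt14 did not. Krt15, a keratin of basal and stem cells in several epithelia, rose from 62675 ± 3724 on day 1 to 302633 ± 29307 on day 3, and Ngfr, a neurotrophin receptor that marks tracheal basal cells, from 359 ± 32.2 to 1581 ± 110. Dapl1, linked to early epithelial differentiation, rose again from day 3 to day 5 (log2 change 2.61, adjusted p = 3.8e-05). Among fluid transport genes, whose list passed in neither step, Slc5a8, a sodium-coupled monocarboxylate transporter, rose from 46.7 ± 5.91 on day 3 to 825 ± 81.4 on day 5, and Kcne3, a potassium channel subunit that aids chloride secretion, to 825 ± 59.5 from 106 ± 21.6. The water channel Aqp4 reached 1065 ± 319 on day 5 from 29.2 ± 22.1 on day 1.

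Growth restraint and signalling genes moved singly in lists that passed in none of the 3 comparisons. Sesn1, a stress-induced p53 target, rose from 217 ± 31.2 on day 1 to 1725 ± 116 on day 5, and Btg2, an antiproliferative gene, from 1480 ± 390 to 8660 ± 1162. Pmepa1, a TGF-beta target that restrains the pathway, rose from 27.5 ± 2.78 to 953 ± 91.5, while the BMP target Id3 fell by 4.18 on the log2 scale from day 3 to day 5 (adjusted p = 6.0e-05). Egr2, an immediate early transcription factor, rose from 2.92 ± 1.17 on day 1 to 398 ± 79.5 on day 5. Cxcl15, a chemokine of lung epithelium and a member of the inflammatory list, which passed from day 1 to day 3, rose from 1.44 ± 1.93 to 1262 ± 112 from day 1 to day 5.

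Genes whose last transcript bases lie under a neighbour on the other strand were low on day 3. Their median change from day 1 was lower by 0.98 (difference −0.98, 99% interval −1.37 to −0.72) than that of genes covered at the first bases alone, and reads drawn mostly from transcript ends on day 3 may account for this. Another counting rule for overlapping genes on day 3 would also lower genes covered at the first bases alone, if reads fell there. Those genes stood 0.12 (−0.03 to 0.37) from genes without overlap. With reads mostly from the last bases, few would fall at the first, so this test cannot set such a rule aside. From day 1 to day 3, mt-Atp8 changed by −3.15 and mt-Atp6 by 0.22, and mt-Nd4l differed from mt-Nd4 by −2.41 (SE 0.59), so a change in transcription of the transcript each pair shares cannot alone account for that step. On day 5, mt-Atp8 stood at 4.35 ± 2.45% of mt-Atp6, mt-Nd4l at 4.84 ± 3.62% of mt-Nd4 (17.3 ± 1.78% and 18.6 ± 1.32% on day 1), and the covered genes at a median of 0.21 from each gene's mean (0.42 on day 1, −0.61 on day 3), but these 3 values were highest in day 5 replicate 1 and were 2.94%, 2.75% and 0.06 without it, so whether the 2 patterns go together on day 5 stays open, and no biological explanation was tested.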
